A study of Mus musculus with 2 samples.

How the data were processed

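Genomic DNA of 2 libraries, 1 of Tcf3-deficient pre-pro-B cells and 1 of Rag1-deficient pro-B cells, was sonicated, ligated to adapters, bisulfite converted and sequenced on a HiSeq, per the labels' protocols. The genotype label of the pro-B library also names E2A, next to Rag1, while its cell type label names Rag1 alone, which was followed; neither genotype was checked. The deposited files give, for both cytosines of each CpG, counts of methylated and of unmethylated calls. The tools named are Bismark 0.7.12, Bowtie2 2.1.0 and HOMER, with build mm9, per the submitters' processing notes. Their order and settings, read trimming, removal of duplicate reads and other filters are not given in the sources used here. Unremoved duplicates would make calls depend on each other and intervals too narrow. The methylated column was recognised from the values, since it held 81.6% and 82.4% of all calls and 0.441% and 0.428% of mitochondrial calls. The low mitochondrial level also bounds incomplete conversion of mitochondrial DNA, though not within single nuclear regions.

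Both files listed the same sites. Calls of the 2 strands of each of 21722921 CpGs were summed. The main measurement used the 20364700 autosomal CpGs, since the libraries differ in sex chromosomes, and kept the 16432698 with at least 5 calls in both libraries, which is 80.7% of them. A level is methylated calls over all calls. CpGs deeper than 5 times the library median, 4139 in pre-pro-B and 4197 in pro-B, held 10.0% and 8.35% of autosomal calls and were kept in the main values; they were left out of relative depth, of levels per chromosome (which use all other CpGs with calls) except on mitochondrial DNA, and of the comparisons by flanking base and by CpG density.

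Non-overlapping 1 kb windows with at least 4 such CpGs were tested with a two-sided Fisher's exact test on summed calls, with Benjamini-Hochberg adjustment over all windows. A window was called at an adjusted p under 0.05 and a difference of at least 30 points. With 1 library per group the test speaks of these libraries only, and calls from one read are not independent. Low-methylated regions were runs of at least 4 CpGs whose running mean over 3 CpGs was under 50%, and runs of at least 30 CpGs were called unmethylated regions. Tests of such regions between libraries used the calls that defined them, so they are biased toward a difference. The planned rule named the 5 called windows per direction with the largest difference. These choices and most alternatives were set before the data were examined.

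Several choices were made after the data were seen. No genome sequence or gene annotation of the files' build was used here, so promoters, gene lists, cell type markers, gene bodies, sequence-based CpG islands, and coverage of Tcf3 and Rag1 were not analysed here, and regions are given by coordinates. As a substitute for islands, CpG-dense stretches were defined as 15 or more listed CpGs within 200 bp, merged where they overlapped, after the number of stretches under several cutoffs had been seen; 23379 of 30364 had at least 5 measured CpGs and were tested like windows. A run was ended at gaps over 1000 bp. The stretches, long unmethylated regions, clusters, comparisons by CpG density and flanking base, single CpGs and stretches without calls, and all regions listed from them, were also chosen after seeing the data. Single CpGs were those at 10% or less in one library and at least 70% in the other, with both neighbours at least 70% in both. Blocks of them were 1 Mb bins with at least 200 evaluated CpGs and 20 or more such CpGs per 10000, a threshold set after viewing the rates.

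The interval of the ratio of shares outside and inside blocks is a log-normal one. It takes stretches as independent, although those in the same megabase share block status, so it is likely too narrow. The scripts were tested on simulated calls with the real depths of chromosome 19. Of 100 windows changed by 40 points, 94 were called, of 100 changed by 60 points 99, and 1 of 44020 unchanged windows was called. Changed windows were drawn from those with a mean level of 80% or more, so recovery at lower levels was not tested. All 100 planted low-methylated regions were found, and 174 of 179 evaluated planted single CpGs. The simulation drew independent calls, so it does not test dependence within reads. Planted regions were runs of 8 CpGs, and regions and single CpGs were planted on a uniform, high level. Reported low-methylated regions held a median of 5 CpGs in pre-pro-B and 6 in pro-B. Recovery of shorter runs, and false finds in partly methylated sequence, were therefore not tested. Strand against strand within a library served as a second null. Alternatives covered the call minimum, excess depth, thinning to equal depth, window size, difference and region thresholds. Analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.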

Results

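Whole-genome bisulfite sequencing measured CpG methylation in cultured mouse B cell progenitors at an early and a later stage. Per the labels, pre-pro-B cells lacked Tcf3 (E2A), a transcription factor of early B cell development, and were grown from fetal liver with IL7, SCF and FLT3L on S17 stromal cells. Pro-B cells were Rag1-deficient per the labels, although their genotype label also names E2A. Rag1 is a recombinase of antigen receptor genes, and neither genotype was checked. The pro-B cells were grown for 7 days with IL7 and SCF after enrichment of bone marrow for the B cell marker B220. Each group held 1 library, so no difference below has a replicate check. The pre-pro-B library held 230807469 CpG calls and the pro-B library 268660596. Median depth per autosomal CpG was 10 calls in pre-pro-B and 12 in pro-B, and 7.30% and 7.23% of autosomal CpGs had no call. Intervals of levels are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. Every test compares these 2 libraries, not the conditions. Words such as rise and fall give the pro-B level relative to pre-pro-B, and no cells were followed over time. Genotype, tissue, culture and sex chromosomes differ along with stage, so their effects cannot be told apart. Coordinates refer to mouse build mm9.

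The comparison asked how DNA methylation differed between the pre-pro-B and the pro-B cells. CpG-dense stretches were far less methylated in pro-B, while most of the remaining genome was slightly more methylated. In CpG-dense stretches the methylation level was 36.7% (interval 36.6 to 36.7) in pre-pro-B and 12.1% (12.1 to 12.1) in pro-B, over 971749 CpGs. In the 2 kb on either side it was 73.3% in pre-pro-B and 62.0% in pro-B, a difference of -11.3 points that was -5.22 points at 12 and -17.1 points at 20 CpGs in 200 bp. At the remaining 14439350 CpGs it was 84.9% in pre-pro-B and 88.1% in pro-B. These opposite shifts nearly cancelled in the genome-wide level, which was 81.99% (81.98 to 81.99) in pre-pro-B and 82.84% (82.84 to 82.85) in pro-B over 16432698 autosomal CpGs with at least 5 calls in both libraries. The difference of 0.854 percentage points became 1.51 points when CpGs of excess depth were left out. The 0.854 points were fewer than the gap between the plus and minus strands within pre-pro-B, at 83.97% and 82.95%, while the 1.51 points were more. That gap was measured over 5441967 CpGs, so the sets of CpGs differ. Intermediate CpGs, at 10 to 70% methylation, made up 14.1% of CpGs in pre-pro-B and 9.58% in pro-B. Without CpGs of excess depth the level was higher in pro-B on 17 of the 19 autosomes and lower on chromosomes 11 and 19. With all calls it was higher on 14 autosomes, and chromosomes 2, 9 and 17 were also lower.

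A large set of CpG-dense stretches was methylated in pre-pro-B and unmethylated in pro-B. Of 23379 autosomal stretches tested, 7692 were lower in pro-B by at least 30 points and 22 were higher (two-sided Fisher's exact test on calls, Benjamini-Hochberg adjusted). The lower stretches had a median level of 91.1% (quartiles 81.1 and 95.6) in pre-pro-B and 4.485% (2.299 and 9.002) in pro-B. Of these, 5902 (76.7%) stood at 80% or more in pre-pro-B and 6828 (88.8%) under 20% in pro-B. Both libraries were under 20% at 9923 stretches and over 80% at 4946. Among the 17092 stretches under 20% in pro-B, 58.1% were also under 20% in pre-pro-B and 29.8% were at 80% or more there.

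**Figure D1:**
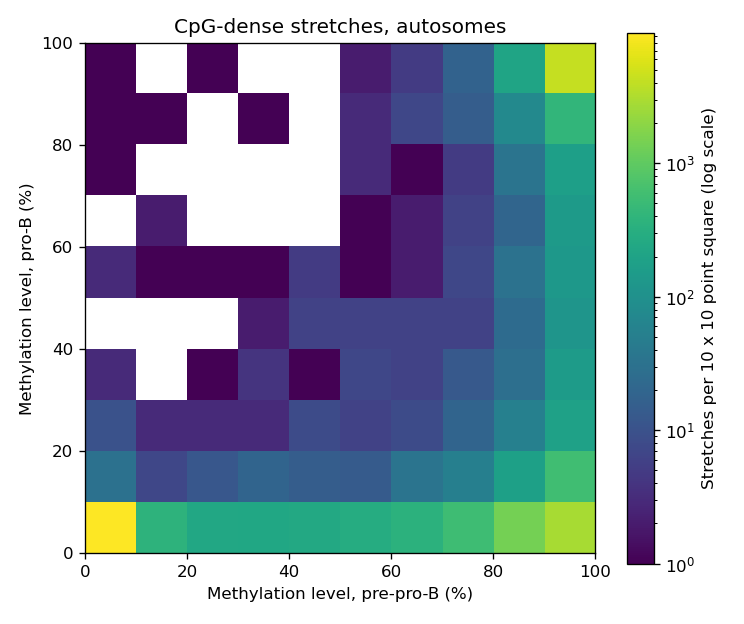
Methylation level of CpG-dense autosomal stretches in pre-pro-B (x axis, %) against pro-B (y axis, %); colour gives the number of stretches per square of 10 by 10 points on a log scale, and white squares hold none. Stretches gather at low levels in both libraries, at high levels in both, and along the lower edge, where 5080 were over 80% in pre-pro-B and under 20% in pro-B; 3 lay in the opposite corner.

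The 6 lower stretches with the most measured CpGs lay on chromosomes 11, 5, 8, 2 and 7. At chromosome 11 from 82743564 to 82746958, with 405 measured CpGs, the level was 97.7% (97.1 to 98.1) in pre-pro-B and 8.18% (7.42 to 8.99) in pro-B. The stretch at chromosome 2 from 146046915 to 146049491 stood at 93.0% (91.9 to 94.0) and 1.88% (1.41 to 2.45). At chromosome 7 from 75095535 to 75098363 the level was 93.6% (92.6 to 94.5) in pre-pro-B and 0.486% (0.251 to 0.847) in pro-B, in a part of the chromosome with raised depth in pre-pro-B. The other 3 kept more methylation in pro-B: chromosome 5 from 144014639 to 144017028 went from 98.3% to 17.1% (15.9 to 18.4), chromosome 8 from 72404746 to 72407171 from 97.9% to 27.8% (26.3 to 29.3), and chromosome 7 from 150644841 to 150647458, also in the part with raised depth, from 96.8% to 44.2% (42.3 to 46.1). Of the 6 higher stretches with the most measured CpGs, those on chromosomes 12, 11 and 10, which had the most, rose from 8.48%, 11.7% and 8.61% in pre-pro-B to 55.9%, 61.5% and 54.1% in pro-B. Chromosome 5 from 143575442 to 143575714 had 0.309% (0.00781 to 1.71) in pre-pro-B and 70.7% (64.4 to 76.5) in pro-B. This stretch and the lower one on chromosome 5 lay near the chromosome's end, where depth in pre-pro-B relative to pro-B was also raised. The stretch at chromosome 8 from 123010302 to 123010565 had 12.3% (7.54 to 18.5) and 84.1% (77.7 to 89.3), and that on chromosome 13 had 26.5% and 56.7%. Levels of 35 to 65% in both libraries occurred at 35 stretches. The one with the most measured CpGs, at chromosome 18 from 13131640 to 13132929, stood at 47.1% (44.2 to 50.1) and 48.7% (45.9 to 51.4). Requiring 20 CpGs in 200 bp lowered the counts to 5056 lower and 3 higher stretches, and 12 CpGs in 200 bp gave 113 higher ones.

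In 1 kb windows the differences ran both ways and split by CpG content. Of 1615369 windows tested, 37306 were lower in pro-B and 74567 higher, each by at least 30 points. Lower windows held a median of 15 CpGs and had median levels of 86.9% in pre-pro-B and 32.4% in pro-B. Higher windows held a median of 5 CpGs and had median levels of 51.9% in pre-pro-B and 90.6% in pro-B. CpG-dense stretches overlapped 28.1% of the lower windows and 0.0818% of the higher ones. The direction of the split depended on settings: at 10 calls per CpG there were 30288 lower and 25839 higher windows, at 50 points 16244 and 8152, and in 500 bp windows 68105 and 57333. One strand against the other within a library, where no cell difference exists, gave 0.342 calls per 1000 windows in pre-pro-B and 0.228 in pro-B, against 68.8 per 1000 between the libraries on the plus strand alone. On that strand 30378 windows were lower and 27160 higher, and on the minus strand 30408 and 27130. The comparison of strands within a library covers counting and strand error only. Differences between separate libraries of the same cells could not be measured.

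The split followed CpG density over larger distances. In the group of 100 kb bins with the fewest CpGs, a median of 466, the level was 77.4% in pre-pro-B and 88.7% in pro-B. There, 5.70 windows per 1000 were lower in pro-B and 120 higher. In the group with the most CpGs, a median of 1337, the level was 81.8% in pre-pro-B and 77.6% in pro-B, with 41.9 windows per 1000 lower and 9.46 higher.

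**Figure D2:**
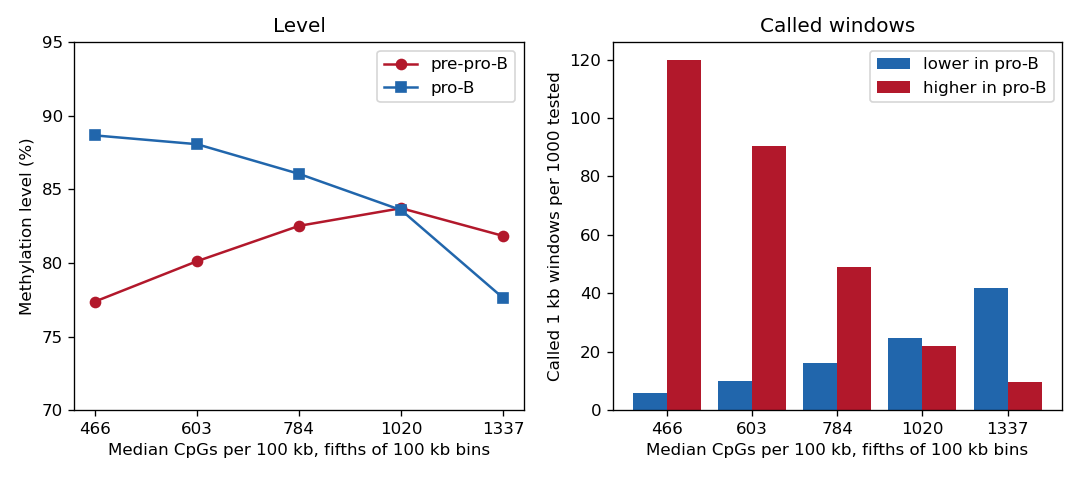
Autosomal 100 kb bins in 5 groups of rising CpG number (x axis, median CpGs per 100 kb); left, methylation level (%) of each library, on an axis starting at 70%; right, called 1 kb windows per 1000 tested. From the sparsest to the densest group, the pro-B level went from 88.7% to 77.6% and windows higher in pro-B from 120 to 9.46 per 1000.

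Some 100 kb bins held at least 10 called windows of the same direction, although no expected number of such bins was computed. Of the windows lower in pro-B, 17.9% lay in the 449 bins of 100 kb with at least 10 of them, and of the higher windows 16.3% lay in 1061 such bins. The bin with the most lower windows was chromosome 2 from 74500001 to 74600000, where 71 of 94 windows were lower and 1 higher. Its level was 83.0% (82.4 to 83.5) in pre-pro-B and 18.9% (18.4 to 19.3) in pro-B. Adjacent bins at chromosome 15 from 102700001 to 102900000 held 48 and 44 lower windows, chromosome 9 from 91200001 to 91300000 held 43, chromosome 17 from 86000001 to 86100000 held 42 and chromosome 6 from 52200001 to 52300000 held 39. The bins on chromosomes 2 and 17 lay in megabases with 79.1 and 63.4 single unmethylated CpGs per 10000 in pro-B, against a median of 2.25. Bins with at least 20 lower windows numbered 68, and 1 bin had at least 20 higher windows. That bin, chromosome 16 from 85300001 to 85400000, held 20 higher windows of 78, at 73.8% in pre-pro-B and 91.6% in pro-B.

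The largest single falls reached nearly the whole scale. At chromosome 8 from 107778001 to 107779000 the level was 98.6% (97.6 to 99.3; 874 calls) in pre-pro-B and 0.594% (0.193 to 1.38; 842 calls) in pro-B. The window at chromosome 13 from 99125001 to 99126000 had 98.4% (97.4 to 99.1) and 0.454% (0.147 to 1.06). Windows at chromosome 5 from 76231001 to 76232000 and chromosome 11 from 97914001 to 97915000 fell by 97.9 points each. A window of 4 CpGs at chromosome 3 from 21024001 to 21025000 fell by 98.0 points, in a megabase with 32.6 single unmethylated CpGs per 10000 in pro-B. The largest rises were in windows of 4 to 16 CpGs. At chromosome 6 from 10640001 to 10641000 none of 62 calls was methylated in pre-pro-B (interval 0 to 5.78%) and the level was 100% (92.5 to 100) in pro-B. Chromosome 17 from 56146001 to 56147000, with 16 CpGs, had 3.09% (1.01 to 7.06) and 99.0% (96.6 to 99.9), in a megabase with 45.5 single unmethylated CpGs per 10000 in pro-B. The others, at chromosome 6 from 68202001, chromosome 12 from 4366001 and chromosome 18 from 6390001, rose by 98.4, 96.6 and 96.1 points.

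Low-methylated regions, the short CpG-poor dips in which regulatory elements are often found, were numerous in both libraries. Pre-pro-B had 59975 and pro-B 53447, of which 28395 and 27724 were specific, that is at least 30 points higher in the other library with an adjusted Fisher p under 0.05. Regions were picked as low in one library and tested on the same calls, so the differences and p-values are biased by that selection, and the counts of specific regions are descriptive. The order reversed with 10 calls per CpG (29345 in pre-pro-B and 35940 in pro-B), with a running mean under 40% (34008 and 41584) and with at least 6 CpGs (24693 and 31850). Of the specific regions, 27793 in pre-pro-B and 24091 in pro-B lay more than 2 kb from any CpG-dense stretch. Their median level was 27.4% in pre-pro-B, against 79.7% in pro-B, for the former, and 21.3% in pro-B, against 76.8% in pre-pro-B, for the latter. Those specific to pre-pro-B held a median of 4 CpGs, the minimum set for a region, over 803 bp. Those specific to pro-B held a median of 6 CpGs over 338 bp. None of these regions was tested as a regulatory element.

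Examples with at least 10 CpGs differed widely between the libraries, and these were listed by a rule set after the data were seen. The region at chromosome 13 from 51257204 to 51257989 was specific to pro-B, at 1.85% (0.384 to 5.32) there and 98.1% (93.4 to 99.8) in pre-pro-B. Chromosome 1 from 196918054 to 196918895 had 4.15% (2.16 to 7.14) in pro-B and 97.9% (95.5 to 99.2) in pre-pro-B. Regions specific to pre-pro-B included chromosome 5 from 101338767 to 101339325, at 4.97% (2.30 to 9.23) there and 95.9% (92.2 to 98.2) in pro-B. Another, at chromosome 1 from 137495014 to 137496054, had 5.03% (2.20 to 9.67) and 93.5% (89.9 to 96.1). The other 3 of the 5 listed per library stood at 0 to 3.20% in pro-B and 95.1 to 97.3% in pre-pro-B, or at 3.04 to 11.0% in pre-pro-B and 88.6 to 97.7% in pro-B; 1 in each set, on chromosomes 11 and 17, lay in a megabase with 214 and 286 single unmethylated CpGs per 10000 in pro-B.

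Unmethylated regions, with at least 30 CpGs, were mostly shared in pre-pro-B and often specific in pro-B. Pre-pro-B had 9306, of which 44 were specific, and pro-B 14606, of which 5531 were specific. Long ones, of at least 3.5 kb and under 20%, numbered 325 in pre-pro-B and 1097 in pro-B. Of the pro-B set, 669 (61.0%) were specific, and the set had a median level of 68.0% in pre-pro-B. The longest in pro-B, at chromosome 2 from 105499536 to 105530777, spanned 31242 bp at 8.749% in pro-B and 80.04% in pre-pro-B, in a megabase with 68.2 single unmethylated CpGs per 10000 in pro-B. In pre-pro-B the longest was at chromosome 6 from 52160960 to 52181109, at 1.30% there and 11.6% in pro-B.

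The libraries differed in their sex chromosomes, with the depths of a female pre-pro-B and a male pro-B library. X levels therefore cannot separate sex from stage. Mean depth on chromosome X relative to the autosomes was 0.707 in pre-pro-B and 0.376 in pro-B, and on chromosome Y 0.00513 and 0.239. The X level was 79.3% (79.2 to 79.3) in pre-pro-B and 84.8% (84.8 to 84.9) in pro-B. Of 504 CpG-dense X stretches under 20% in pro-B, the median level in pre-pro-B was 51.8% (quartiles 39.1 and 91.5), against 2.49% (0.557 and 86.4) for autosomal ones. On mitochondrial DNA 0.441% (0.412 to 0.472) of CpG calls were methylated in pre-pro-B and 0.428% (0.399 to 0.458) in pro-B.

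Depth and single CpGs also separated the libraries along the autosomes. Relative depth on chromosome 7 was 1.23 in pre-pro-B and 0.971 in pro-B, and the excess lay beyond 56 Mb. Raised ratios of pre-pro-B over pro-B depth were not confined to chromosome 7. The 95th percentile of 1 Mb bins on the other autosomes was 1.102. Most bins near the end of chromosome 5 exceeded it, as did runs of bins on chromosomes 12 and 14. The cause of these was not tested. Leaving chromosome 7 out gave 35019 lower and 70295 higher windows. Single CpGs unmethylated between methylated neighbours numbered 77686 in pre-pro-B and 28509 in pro-B among 9647508 evaluated. In pro-B, 366 of 2400 megabases held 92.6% of those in binned regions, among them chromosome 18 from 36 to 75 Mb, chromosome 2 from 36 to 65 Mb and chromosome 14 from 8 to 25 Mb. Within those megabases 36.3 windows per 1000 were lower in pro-B, against 20.8 elsewhere, and 39.6 were higher, against 47.3. These megabases were chosen for CpGs low in pro-B, which also enter the windows. The differences in window rates are therefore partly built in.

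**Figure D3:**
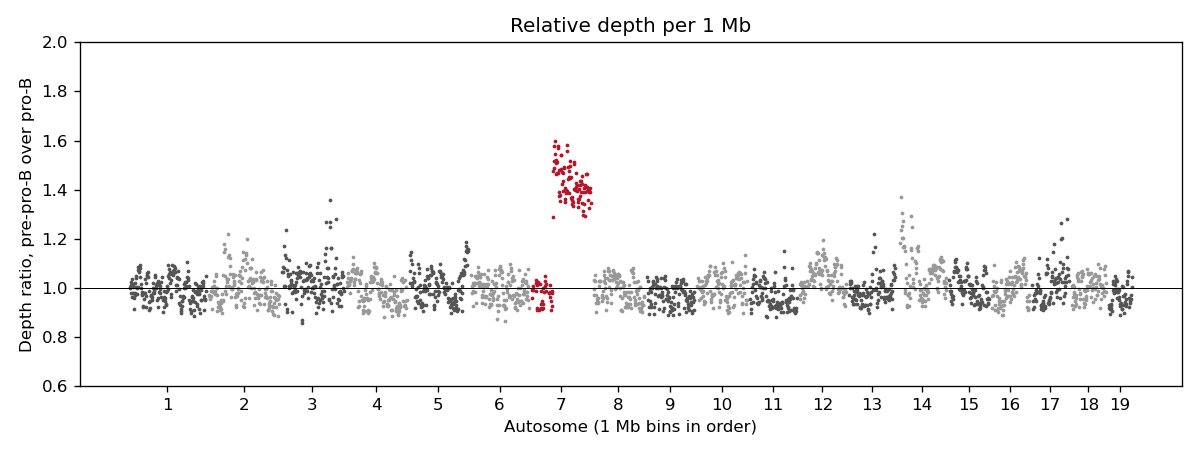
Depth of pre-pro-B over pro-B, each relative to its autosomal mean, per 1 Mb bin (points) along the autosomes (x axis); chromosome 7 is in red. Its bins from 56 Mb onward sit at a median of 1.41, and the bins before that at 0.983.

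**Figure D4:**
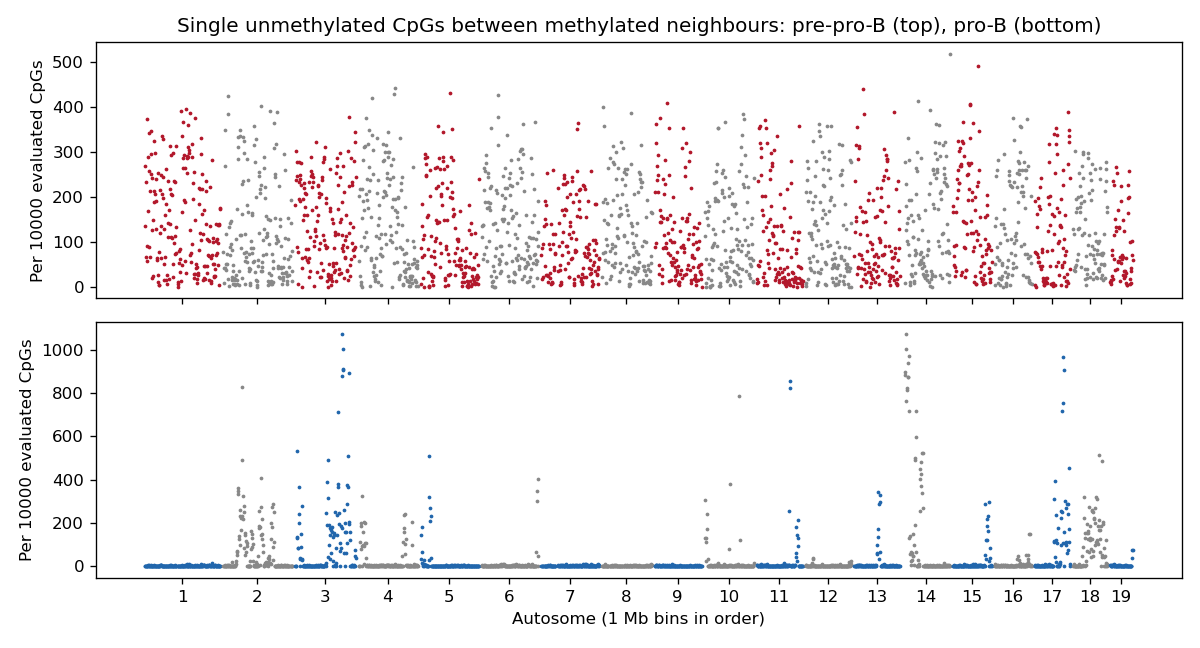
Single unmethylated CpGs per 10000 evaluated (y axis, scales differ) per 1 Mb bin (points) along the autosomes, for pre-pro-B (top) and pro-B (bottom); grey and coloured points alternate by chromosome. Rates are spread over all autosomes in pre-pro-B, with a median of 93.5, and stand in blocks in pro-B, with a median of 2.25.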

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

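Among the tests below, those of strain variants by no-call stretches, of one-strand calls in pro-B alone and of bisulfite conversion were chosen after the result was seen. So were those of dense stretches by pro-B blocks, of cell stage, of base composition and of the distal part of chromosome 7. The ratios set for homozygous variants were written beforehand.

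Of 23379 tested CpG-dense stretches, 7692 were lower in pro-B, most of them methylated in pre-pro-B and unmethylated in pro-B. For these, 3 explanations other than a change in the cells were tested. The mitochondrial methylated share differed by 0.0133 points between the libraries, against incomplete conversion across the whole pre-pro-B library. Mitochondrial calls do not measure conversion within the dense nuclear stretches themselves. Of the stretches lower in pro-B, 76.73% stood at 80% or more in pre-pro-B, against a minority of other cells as the source. The median of 90.91% of their CpGs at 70% or more in pre-pro-B decides nothing about sequence variants, since these stretches were chosen as lower in pro-B, and neither does a ratio of shares outside and inside the pro-B blocks 69.37 times that of single unmethylated CpGs, which define the blocks. Of tested stretches, 32.5% were lower outside the blocks and 35.4% inside, a ratio of 0.9178 (interval 0.873 to 0.965). The ratio argues against variants like those in the blocks as the whole source. Its interval takes stretches as independent and is likely too narrow. With 1 library per group, cell stage, genotype, sex, fetal or adult tissue and culture cannot be told apart.

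Single CpGs unmethylated between methylated neighbours occurred at 80.5 per 10000 in pre-pro-B and 29.6 per 10000 in pro-B, and 81 stretches of at least 20 CpGs had no call in pro-B against 3 in pre-pro-B. Sampling noise as the whole source is argued against in both, since at 15 or more calls the rate was still 48.57 in pre-pro-B and 19.2 in pro-B. Both rates were lower than those over all evaluated CpGs, so noise as a part of the source stays open. In pro-B the single CpGs lay in blocks, such as chromosome 14 from 8 to 25 Mb, and the no-call stretches were 6.563 times as frequent in blocks as listed CpGs. One-strand gaps exceeded those of other CpGs by 7.159 points, against methylation loss alone. Sequence from another strain may therefore be present despite the C57BL/6 label, although CpGs at 10% or less were 1.761 times those at 10 to 30%. This was short of the 2 set for homozygous variants. In pre-pro-B that ratio, of CpGs at 10% or less over those at 10 to 30%, was 0.4733, which argues against homozygous variants. Methylation loss stays open there, because the one-strand excess of 1.141 points lay just outside the bound of 1 point set for it. It lay far below the 3 points set against it. At the same CpGs in pro-B, where they are methylated, the excess was 0.740 points. For the pro-B set, the same CpGs in pre-pro-B had an excess of -0.183 points. No biological explanation beyond methylation loss was tested.

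Chromosome 7 had 1.23 times the autosomal depth in pre-pro-B. Base composition is argued against by its depth of 0.9715 in pro-B, and collapsed repeats were left open by the test set beforehand, with 71.85% of its 1 Mb bins above the 95th percentile of the other autosomes. An extra copy with a steady shift along the chromosome, the prediction written beforehand, failed: the interquartile range of the bins was 5.475 times that of the other autosomes. The profile, seen afterwards, stepped at 56 Mb, with a pre-pro-B over pro-B ratio of 0.983 before it and 1.41 after it; 100% of the distal bins passed the 95th percentile, and the distal over proximal ratio of 1.435 may reflect a gain of that part. That reading was found and tested on the same profile, and whether culture or origin gave rise to it was not tested.

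Chromosome Y had 50411 calls in pro-B and 896 in pre-pro-B. Of X stretches under 20% in pro-B, 51.8% stood at 20 to 60% in pre-pro-B, against 6.36% of autosomal ones. CpGs of excess depth took 10.0% of autosomal calls in pre-pro-B and 8.35% in pro-B.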

How the results depend on the processing

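The tests of dense-stretch cutoffs, median differences, single CpGs, blocks, low-rate bins and chromosome 7 were chosen after seeing the data. The genome-wide difference stayed positive and the dense-stretch difference negative under every alternative run. Within one library, the plus and minus strands stood at 83.97% and 82.95% in pre-pro-B, and at 83.47% and 83.16% in pro-B. The strand gap in pre-pro-B was wider than the genome-wide difference of the main setting, but narrower than that without CpGs of excess depth. It was measured over 5441967 CpGs, against 16432698 in the main setting. The genome-wide difference of 0.854 points was 0.716 at 3 calls, 0.987 at 10 calls, 1.51 without CpGs of excess depth, 0.865 after thinning and 1.39 as an unweighted mean. The dense-stretch difference of -24.5 points was -25.1 at 3 calls, -21.8 at 10 calls, -24.6 without excess depth, -22.0 at 12 and -24.3 at 20 CpGs in 200 bp. In the 2 kb flanks the difference of -11.3 points was -9.89 at 10 calls, -5.22 at 12 and -17.1 at 20 CpGs in 200 bp; at the remaining CpGs the difference of 3.19 points ranged from 2.52 at 10 calls to 4.07 without excess depth. Dense stretches higher in pro-B numbered 7 at 10 calls, 113 at 12 CpGs and 3 at 20 CpGs, where 5056 were lower; 5457 were lower at 10 calls and 10278 at 12 CpGs. Lower and higher windows numbered 63394 and 181508 at 20 points, 16244 and 8152 at 50 points; 68105 were lower in 500 bp and 16814 in 2 kb windows, 25839 were higher at 10 calls, and 44543 were higher when the median CpG also differed by 30 points. Strand against strand, a null, gave 96 and 93 in pre-pro-B, and 100 and 91 in pro-B. The share of higher among called windows, 66.7%, was 46.0% at 10 calls, 33.4% at 50 points and 45.7% in 500 bp windows. Single strands also gave more lower than higher windows, 30378 against 27160 on the plus strand. The median difference was 36.8 points in higher windows and -46.3 points in lower ones, so a cutoff of 50 points kept fewer of the higher ones. The cause at 10 calls, in 500 bp windows and on single strands was not tested, although 10 calls left 950056 windows. Higher windows per 1000 fell from 46.2 to 27.6 with the median rule, to 6.31 in the 153 megabases with under 10 single CpGs per 10000 in both libraries, and to 3.84 there with the median rule; lower ones were 23.1 in the main setting, and 28.9 and 23.2 in those megabases. That restriction is circular for the higher windows, since it keeps megabases where pre-pro-B has few unmethylated single CpGs. Leaving out pro-B blocks gave 20.8 lower and 47.3 higher per 1000. Those blocks were chosen for CpGs low in pro-B, so the smaller number of lower windows is partly built in. Low-methylated regions in pre-pro-B numbered 29345 at 10 calls, 34008 and 115074 at running means under 40% and 60%, and 24693 with 6 CpGs. Pro-B had 35940, 41584, 71841 and 31850 there, so the order of the libraries reversed at 10 calls, at 40% and with 6 CpGs. The causes were not tested.

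Alternatives for promoters, gene lists and targeted gene coverage were not run, because no annotation of the build was used here. No paired analysis was possible because each group has 1 library, and leaving out a library or regrouping libraries would leave no comparison. Depth of 10 and 12 calls per CpG limits single CpGs more than windows.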

Other observations

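The comparisons by flanking base and by neighbouring CpGs were chosen after the data were seen. Outside CpG-dense stretches, the bases next to a CpG went with the size of the difference. CpGs with A or T on both sides and no other CpG within 35 bp stood at 72.2% (72.2 to 72.3) in pre-pro-B and 86.2% (86.2 to 86.2) in pro-B, a difference of 14.0 points over 2338063 CpGs. With other CpGs within 35 bp the difference was 3.36 points. CpGs with C or G on both sides differed by 2.41 points when alone and by -0.566 points when not alone. By motif, TCGA stood at 77.4% in pre-pro-B and 87.9% in pro-B, and GCGC at 93.7% and 94.7%.

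Pre-pro-B cells may have lost methylation in part at lone CpGs between A or T, a hypothesis formed on these data. The difference there exceeded that at CpGs between C or G with close neighbours by 14.57 points, but this restates the values that gave rise to the hypothesis and leaves it open. CpGs between A or T were 62.2% of the single unmethylated CpGs of pre-pro-B, 26.7% of those of pro-B and 28.6% of all evaluated ones. Time in culture, genotype and tissue are confounded here, and none of them was tested as the origin.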
